A study of Arabidopsis thaliana with 11 samples.

How the data were processed

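Gene expression was measured by RNA sequencing in protoplasts sorted by fluorescence from the aerial tissue of 10-day-old Arabidopsis seedlings (Columbia). Per the labels' protocols, plants grew at 25 °C with 16 h of light and 8 h of dark, tissue was digested for 2 h, and fluorescent protoplasts went straight into extraction buffer. Total RNA of about 10 ng per sample, from 4000 to 20000 cells, was enriched with oligo-dT beads and amplified as cDNA by the SPIA method. The labels' description field calls the profiles microarray-based, while the titles and library fields give RNA sequencing, which was followed here. The 11 libraries fall into 5 groups by marker line, which the titles give together with the replicate number.

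The authors deposited log2-scale expression values, normalized over the libraries, in 1 table of 33602 genes and 11 columns, 1 per library. Per the submitters' processing notes, the tools were Bowtie2 and DESeq2, without versions, and the build was TAIR10. The read counter, the annotation and the transformation behind the values are not given in the sources used here. The base of 2 was inferred, because the authors' tool DESeq2 writes its transformed values on that scale and because 2 to the power of the values adds up to between 17236592 and 25175463 per library, the size of a usual read total. Values ran from -4.00 to 21.57, and 2 genes had no value in any library. No whole-number steps were left, so read depth is unknown, no counting interval can be given, and a count test was not possible. A transformation that shrinks low values would make differences of low genes smaller than they were. Every column matched 1 sample by name.

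The fixed design foresaw log2(value + 1) of linear values. The deposited values are already logarithms and were used as they are, and a value with 1 added on the linear scale before the log was kept as an alternative. Genes with 2 to the power of the value at or above 10 (3.32 on the log2 scale) in at least 2 libraries were tested, which left 29850. Gene names came from the TAIR10.1 RefSeq annotation, matched on locus code for 32835 of the 33602 genes, of which 10654 had a symbol. That assembly differs from the authors' build by name, so it was used for names only and no coordinates are printed. The codes of RPS5A and RPS5B had been exchanged in the list of ribosomal genes and were set by the reference's symbols. The guard cell gene known as GC1 has no symbol in the reference and appears as AT1G22690.

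Differences between groups were tested with limma-trend (limma 3.58.1, R 4.3.3): group means of all 11 libraries in 1 fit, moderated variances with a mean trend, and Benjamini-Hochberg adjustment over genes within each comparison at 0.05, two-sided. Log2 differences are given ± the standard error of the fit, group levels as mean ± SD. The fit gives each gene 1 spread for all groups, so the error is understated for a group whose libraries vary more. Of the 7 comparisons, 4 set a stage against the sorted epidermis and share its 2 libraries, so their results are not independent. The other 3 set consecutive stages against each other. An F test over the 4 stages asked which genes vary along the lineage. Gene lists (18, giving 126 tests) were compared with all other genes by camera from limma with a preset correlation of 0.01 between genes, adjusted over all 126 tests, and again with an estimated correlation. The lists were marker line genes, early stomatal lineage regulators, guard mother cell regulators, mature guard cell function, abscisic acid signalling core, mitotic cell cycle, DNA replication, D-type cyclins and CDK inhibitors, photosynthesis, epidermis and cuticle, trichome, vasculature, meristem and leaf primordium growth, wound and touch response, heat shock, cytosolic ribosomal proteins, auxin response and transport, and Polycomb and DNA methylation. The wound and touch response and heat shock lists were planned as markers of the handling of tissue. Whether their shifts came from handling or from the stage was not tested in any comparison. All tests, lists, naming rules and alternatives were fixed before the data were examined unless stated otherwise.

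Named genes are the 4 marker line genes in every group, up to 8 genes in each direction with the largest change per comparison, and up to 4 members of each described list with the smallest adjusted p. The genes with the largest change had to pass the threshold, have a symbol, show no overlap between the libraries of the groups, and lie in the higher group at or above the median of all group means. Further members that passed in a described list are also named, chosen after their values were seen. Such members, as HT1 in E1728G against ML1Y, and the transcript AT3G12502 are not in the counts of named genes over leave-one-out fits. For FGF against MG, 1 gene that met these rules is not reported here.

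The fit was tested on simulated data with 200 changed genes among 29850, in which the spread was taken from the real libraries. At a log2 difference of 3 it recovered 36.4% of the changed genes for SSY against ML1Y, 9.09% for MG and for FGF against ML1Y, 0% for E1728G against ML1Y, 22.7% for MG against SSY, 18.2% for FGF against MG and 19.7% for E1728G against FGF. At a difference of 2 it recovered at most 4.48% of them, for SSY against ML1Y, and at a difference of 1 none in any comparison. Each comparison had 1 simulated set with 66 genes at a difference of 3, so unlike shares between comparisons may reflect the draw. The adjusted threshold is also stricter with 200 changed genes than where more genes changed. In the data, 728 genes passed for E1728G against ML1Y, the smallest at an absolute difference of 1.85. The shares are therefore no estimate of power in the data. Alternatives covered pseudocounts of 0.1, 1 and 10, no filter on low values and a filter at 50, quantile normalization, trimmed mean (TMM) scaling with 30% of the ratios and 5% of the levels trimmed at each end, robust moderation, fits of only the groups compared, the replicate number as a block, a 2-fold minimum, leaving out each library, library weights, and leaving out all SSY libraries. Nothing in the labels says that replicates came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.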

Results

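The series followed gene expression along the stomatal lineage of the Arabidopsis leaf epidermis, in which a protodermal cell becomes a meristemoid, then a guard mother cell, and then a pair of guard cells. Protoplasts were sorted from 5 marker lines. ML1Y (a membrane-bound YFP under the ML1 promoter) marks the whole epidermis and had 2 libraries. SSY (a SPCH-YFP fusion under the SPCH promoter) marks the early stage and had 3 libraries. MG (nuclear GFP under the MUTE promoter), FGF (a GFP-FAMA fusion under the FAMA promoter) and E1728G (an enhancer trap line) mark the middle and late precursors and mature guard cells, with 2 libraries each. Depth is unknown, because the deposited values are normalized log2 values.

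Libraries of a group differed from the group mean by a root mean square, scaled for group size, of 0.456 log2 units in ML1Y, 0.744 in MG, 0.608 in FGF and 0.668 in E1728G, and by 0.892 to 0.917 in SSY. The interquartile range of the values over genes was 2.13 to 2.29 in the SSY libraries and 2.67 to 3.28 in the others. The highest rank correlation of an SSY library with any other library, across genes, was 0.805 to 0.813, against 0.891 to 0.946 for the remaining libraries. Some libraries lay closest to another group. SSY replicate 1 correlated more with FGF replicate 1 (0.813) than with SSY replicates 2 (0.791) and 3 (0.799). MG replicate 1 did so with FGF replicate 1 (0.907, against 0.891 with MG replicate 2). FGF replicate 1 and E1728G replicate 2 correlated at 0.934, against 0.914 and 0.900 with their own replicates. The rest correlated most with a library of their own group. The first principal component held 24.3% of the variance and placed the 3 SSY libraries apart from the 8 others.

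The genes behind the marker lines were read first. MUTE (AT3G06120), the bHLH factor that ends the divisions of the meristemoid, stood at 8.75 ± 1.57 (SD, n = 2) in MG and at 4.54 ± 0.48 (n = 2) in ML1Y, a log2 difference of 4.21 ± 0.64 (limma adjusted p = 0.00467). FAMA (AT3G24140), the bHLH factor of the last division and of guard cell identity, stood at 14.47 ± 0.62 (n = 2) in FGF and 8.59 ± 0.42 (n = 2) in ML1Y, which is 58.8-fold (log2 difference 5.88 ± 0.82, adjusted p = 0.0024). FAMA was also higher in SSY than in ML1Y, at 11.55 ± 0.87 (n = 3; adjusted p = 0.0317). SPCH (AT5G53210), the factor that starts the lineage, did not pass in any comparison and had its lowest group mean in SSY, the line built on it. It stood at 5.58 ± 0.50 (n = 3) in SSY, 6.14 ± 0.32 in ML1Y, 6.34 ± 1.11 in MG, 7.47 ± 1.12 in FGF and 6.09 ± 0.39 in E1728G (n = 2 each). For SSY against ML1Y its log2 difference was -0.56 ± 0.62 (adjusted p = 0.649). ATML1 (AT4G21750), the epidermal homeodomain gene, did not pass in any comparison and lay between 7.80 in E1728G and 9.42 in MG. The SSY and FGF lines carry fusions with the SPCH and FAMA coding sequences, whose transcripts cannot be told from those of the native genes in these values. MUTE in MG lost its call without ML1Y replicate 2 or MG replicate 2, and FAMA in FGF without ML1Y replicate 2 or FGF replicate 2.

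**Figure D1:**
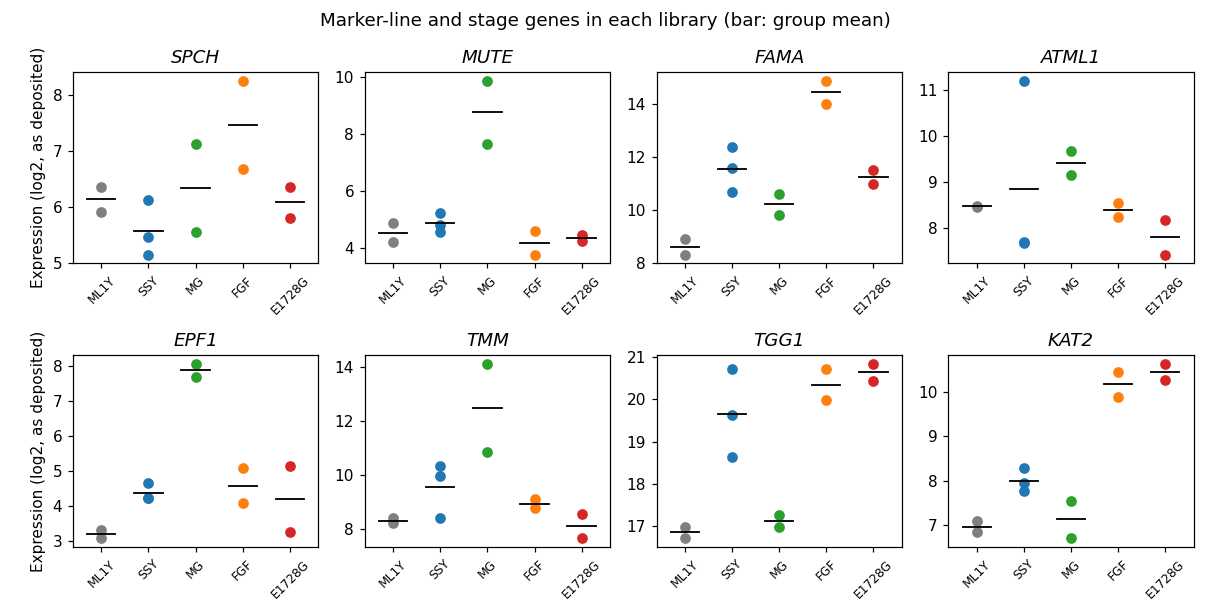
Deposited log2 expression (vertical axes) of 8 genes in each library, by marker line (horizontal axes), with a bar at each group mean; points are single libraries. MUTE and EPF1 were highest in MG (group means 8.75 and 7.86), FAMA in FGF (14.47), and TGG1 and KAT2 in E1728G (20.64 and 10.45), while SPCH averaged 5.58 in SSY.

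SSY, the line for the early stage, was compared with the whole epidermis. Photosynthesis transcripts fell: all 22 members of that list passed, with a median log2 difference of -5.20 (camera adjusted p = 1.24e-28, adjusted p = 0.00585 with an estimated correlation). LHCA4, an antenna protein of photosystem I, went from 16.07 ± 0.35 in ML1Y (n = 2) to 8.39 ± 0.60 in SSY (n = 3), and LHCB2.2, LHCB2.1 and LHCB6 fell by 6.59, 6.50 and 5.90 on the log2 scale. Genes of carbon metabolism around photosynthesis moved with them: the carbonic anhydrase CA2 (-8.04 ± 0.71), the glycolate oxidase GOX1 (-7.78 ± 0.69), the chloroplast aldolase FBA2 (-7.28 ± 0.76) and the chloroplast dehydrogenase GAPA-2 (-6.72 ± 0.73). ASN1, an asparagine synthetase, had the largest drop of the named genes (-8.56 ± 0.70, adjusted p = 6.63e-05), followed among the others by the antenna gene LHB1B1 (-7.76) and the thiamine synthesis gene THI1 (-6.83).

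Of the lineage lists, TGG1 (AT5G26000), the myrosinase abundant in guard cells and myrosin cells, rose to 19.66 ± 1.04 in SSY from 16.85 ± 0.19 (adjusted p = 0.00372). It was the only one of 24 mature guard cell genes that passed (1 rose adjusted over the list alone, and 1 fell). Of the 24, 18 had positive differences, without a call for the list (camera adjusted p = 0.103). FAMA was the only one of 11 guard mother cell regulators that passed (1 adjusted over the list alone). Of the 11, 10 had positive differences, again without a call (camera adjusted p = 0.0535). Among 16 early lineage regulators, the receptor kinase ER fell (-2.47 ± 0.59) and none rose (3 rose and 1 fell adjusted over the list alone). That list had no call either, with 12 positive differences (camera adjusted p = 0.153). The touch genes CML38 (-4.62) and TCH3 (8.74 in SSY, 12.74 in ML1Y) fell. All 13 wound and touch response genes, planned as markers of the handling of tissue, had negative differences (2 fell, 4 adjusted over the list alone). The camera adjusted p was 0.000157 (adjusted p = 0.154 with an estimated correlation). Of 14 cytosolic ribosomal protein genes RPL5B and RPS21B fell (2 adjusted over the list alone). The list was lower (camera adjusted p = 0.0179, adjusted p = 0.271 with an estimated correlation), a call that ended without SSY replicate 3 and with the filter at 50. Single members of other lists passed: the D-type cyclins CYCD3;1 (-2.20) and CYCD3;2 (-2.71), the phosphatase HAB2 (-2.57), the auxin response gene IAA2 (-2.73) and the xylem protease XCP2 (-1.96) fell. The trichome factor TTG2 (3.12), the kinase AUR2 (7.53 in SSY, 5.43 in ML1Y) and the chaperone HSP90.1 (2.39) rose. Among the named genes the largest rises belonged to the defensin-like genes LCR6 (4.82 ± 0.70) and LCR20 (4.51 ± 0.64), the xylem-related TED6 (3.70), the extensin EXT4 (3.41), the chromatin remodelling gene CHR18 (3.41), PP2-A3 (3.40), the ubiquitin ligase RMA1 (3.38) and FZR3 (11.70 in SSY, 8.40 in ML1Y).

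In all, 239 genes were higher and 1418 lower in SSY than in ML1Y. The count was 299 to 1849 when single libraries were left out, and it fell to 450 (22 higher) without ML1Y replicate 1 and to 299 (16 higher) without ML1Y replicate 2. Without SSY replicate 1, 486 genes were higher and 1363 lower, and a fit of only the groups compared gave 32 and 869. Of 34 named genes that passed, 14 did so in every leave-one-out fit: LCR6, LCR20, ASN1, CA2, GOX1, LHB1B1, LHCA4, FBA2, THI1, GAPA-2, LHCB2.2, LHCB2.1, LHCB6 and CML38.

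The middle stage was compared with the epidermis in the same way. EPF1 (AT2G20875), a secreted peptide that spaces stomata, went from 3.19 ± 0.15 (n = 2) to 7.86 ± 0.26 (n = 2) (adjusted p = 0.00168), and MUTE rose as given above. SDD1, a subtilisin-type protease that limits stomatal density, rose by 4.81 ± 1.05 with a wide spread in MG (11.73 ± 2.89, n = 2). Of 11 guard mother cell regulators 2 rose (3 adjusted over the list alone), and the list was raised (camera adjusted p = 0.000157, adjusted p = 0.0635 with an estimated correlation). Of 16 early lineage regulators 1 rose (7 adjusted over the list alone), and that list was raised too (camera adjusted p = 6.24e-06, adjusted p = 0.0635 with an estimated correlation). Photosynthesis genes were again low, with a median of -4.30 (camera adjusted p = 4.66e-35, adjusted p = 0.00585 with an estimated correlation). Of 22 members 16 fell (22 adjusted over the list alone), among them RBCS1B (-6.37), LHCA4 (-5.47), LHCB1.2 (-5.84) and LHCB1.3 (-5.57).

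The epidermis and cuticle list was raised with no member past the threshold (5 of 12 adjusted over the list alone, median 1.81). Its camera adjusted p was 4.44e-06 (adjusted p = 0.258 with an estimated correlation). The mitotic list was raised by the preset test with 0 of 25 members past the threshold, 0 adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.359 with an estimated correlation). So was the DNA replication list, with 0 of 15 members and 1 adjusted over the list alone (camera adjusted p = 0.0268, adjusted p = 0.406 with an estimated correlation). Heat shock genes, also planned as markers of handling, were raised with 0 of 8 past the threshold, 0 adjusted over the list alone (camera adjusted p = 0.000304, adjusted p = 0.377 with an estimated correlation). Of the 4 marker line genes 1 rose, 1 adjusted over the list alone (camera adjusted p = 0.0118, adjusted p = 0.189 with an estimated correlation). The gene that rose was MUTE, whose promoter marks the sorted cells, so the call is not independent of the sort. Apart from these lists, the cutin hydroxylase CYP86A8 (3.96), the prohibitin PHB6 (3.74), NIP1;2 (3.52), the DNA primase gene POLA3 (3.44) and MEE69 (3.44) rose. Photorespiratory genes fell, with GOX1 (-7.29), GGT1 (-6.48) and HPR (-6.04), as did CA2 (-6.73), LHB1B1 (-6.40), the peroxisome gene PEX11D (-6.29), THI1 (-6.07) and XCP2 (-2.23).

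MG had 56 genes higher and 426 lower than ML1Y (36 to 629 genes in total when single libraries were left out, with 143 without ML1Y replicate 1 (7 higher), 36 without ML1Y replicate 2 (1 higher) and 99 without MG replicate 2 (28 higher)). Without MG replicate 1 the excess of lower genes was gone, with 308 higher and 321 lower. Of 20 named genes that passed, 9 did so in every leave-one-out fit, namely EPF1, GOX1, CA2, GGT1, LHB1B1, RBCS1B, PEX11D, THI1 and HPR. Without MG replicate 1 the mitotic, DNA replication, heat shock and marker line lists lost their calls, and without ML1Y replicate 1 the DNA replication list did.

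In the late stage, guard cell genes were higher than in the epidermis. TGG1 reached 20.35 ± 0.52 (n = 2), a rise of 3.50 ± 0.53 (adjusted p = 0.00355), the potassium channel KAT2 rose by 3.20 ± 0.69, the kinase HT1, which acts in the stomatal response to carbon dioxide, by 3.18 ± 0.73, and TGG2 by 3.32 ± 0.81. They were the 4 of 24 mature guard cell genes that passed (8 adjusted over the list alone). Of the 24 genes 23 had a positive difference, with a median of 1.68 (camera adjusted p = 5.1e-10, adjusted p = 0.0186 with an estimated correlation). Photosynthesis genes were low, with a median of -4.20 (camera adjusted p = 1.76e-31, adjusted p = 0.00585 with an estimated correlation). Of 22 members 14 fell (21 adjusted over the list alone), with RBCS2B (-6.22), LHCB1.2 (-6.20), RBCS1B (-5.85) and LHCA4 (-5.30) among them. The RBCS genes and the LHCB1 genes have near-identical copies, so the split of reads within each of these families is uncertain. TGG1 and TGG2 are related genes, and whether reads were shared between them was not tested.

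Beside FAMA, the lipase-like GLIP5 (4.28), the proteinase inhibitor TI2 (3.86), the co-chaperone Hop3 (3.71), the small heat shock protein ATHSP22.0 (3.63), FLA11 (3.47) and the protein kinase SIP3 (3.41) rose. The 8 heat shock genes were all higher, though 0 passed (8 adjusted over the list alone). Their median was 2.39 (camera adjusted p = 6.84e-07, adjusted p = 0.261 with an estimated correlation). All 14 ribosomal protein genes had negative differences, and RPS21B fell by 2.37 (2 adjusted over the list alone). The list was lower (camera adjusted p = 0.000244, adjusted p = 0.179 with an estimated correlation). Of 17 auxin genes 0 passed (1 adjusted over the list alone). The list was lower by the preset test (camera adjusted p = 0.0196, adjusted p = 0.189 with an estimated correlation), a call that ended without FGF replicate 1. CYCD3;1 (-2.77), CYCD3;2 (-3.29), ER (-2.68) and XCP2 (-2.66) fell. So did GOX1 (-6.62), LHB1B1 (-6.34), CA2 (-6.17), FBA2 (-6.16), the plastid ribosomal protein gene emb1473 (-6.00) and FBA1 (-5.95).

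FGF had 66 genes higher and 563 lower than ML1Y (87 to 719 in total when single libraries were left out, with 213 without ML1Y replicate 1 (5 higher), 87 without ML1Y replicate 2 (3 higher), 265 without FGF replicate 1 (68 higher) and 103 without FGF replicate 2 (11 higher)). Of 26 named genes that passed, 8 did so in every leave-one-out fit: FLA11, GOX1, LHB1B1, RBCS2B, CA2, emb1473, FBA1 and RBCS1B.

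Mature guard cells were compared with the epidermis last. Of 24 mature guard cell genes 5 rose (8 adjusted over the list alone), with a median over the list of 1.48 (camera adjusted p = 8.48e-09, adjusted p = 0.0229 with an estimated correlation). TGG1 stood at 20.64 ± 0.29 (n = 2; adjusted p = 0.00248), TGG2 rose by 4.29 ± 0.81, the proton pump AHA5 by 3.62 ± 0.75, KAT2 by 3.48 ± 0.69 and HT1 by 3.00 ± 0.73. ICE1 (3.46 ± 0.84), the bHLH partner of the stage factors, rose, while ER fell (-3.02 ± 0.65). They were the members of the early lineage list that passed (1 rose and 1 fell adjusted over the list alone). Photosynthesis genes were low, with a median of -3.87 (camera adjusted p = 1.98e-27, adjusted p = 0.00585 with an estimated correlation). Of 22 members 15 fell (21 adjusted over the list alone), with RBCS2B (-5.98), RBCS1B (-5.57), RCA (-5.36) and LHCA4 (-4.93).

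Among genes with a symbol that met the naming rules, the largest rise was in the basic chitinase gene HCHIB (6.14 ± 0.88). It overlaps an antisense transcript without a symbol, AT3G12502, which rose by 6.96 ± 0.76 (adjusted p = 0.00105). The strand of the libraries is not given in the sources used here, so reads of HCHIB and AT3G12502 cannot be told apart. UGT73D1 (3.97), the transporter ABCG21 (3.85), the brassinosteroid receptor gene BRL3 (3.85), GSTU1 (3.80), the AP2-type factor TOE3 (3.76) and the cyclin CYCB2;4 (3.26) also rose. ASN1 (-7.51), CA2 (-6.33), GOX1 (-6.28), the Calvin cycle gene SBPASE (-6.15), PP2-A5 (-5.73), GGT1 (-5.55), IAA2 (-4.24), TCH3 (-3.49), CYCD3;2 (-3.44), XCP2 (-3.01) and CYCD3;1 (-2.78) fell. Of 8 heat shock genes 0 passed (0 adjusted over the list alone), and the list was higher by the preset test (camera adjusted p = 0.0143, adjusted p = 0.463 with an estimated correlation). Of 14 ribosomal protein genes 0 passed (2 adjusted over the list alone), and the list was lower (camera adjusted p = 0.0143, adjusted p = 0.261 with an estimated correlation). The heat shock call ended and changed direction without E1728G replicate 2. It also ended without ML1Y replicate 1 and with quantile normalization, and the ribosomal call ended without E1728G replicate 2.

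E1728G had 104 genes higher and 624 lower than ML1Y (93 to 821 in total when single libraries were left out, with 190 without ML1Y replicate 1 (12 higher), 93 without ML1Y replicate 2 (7 higher) and 105 without E1728G replicate 1 (7 higher)). Without E1728G replicate 2 the split was more even, with 243 higher and 299 lower. Of 28 named genes that passed, 8 did so in every leave-one-out fit: HCHIB, ASN1, CA2, GOX1, SBPASE, RBCS2B, PP2-A5 and GGT1.

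**Figure D2:**
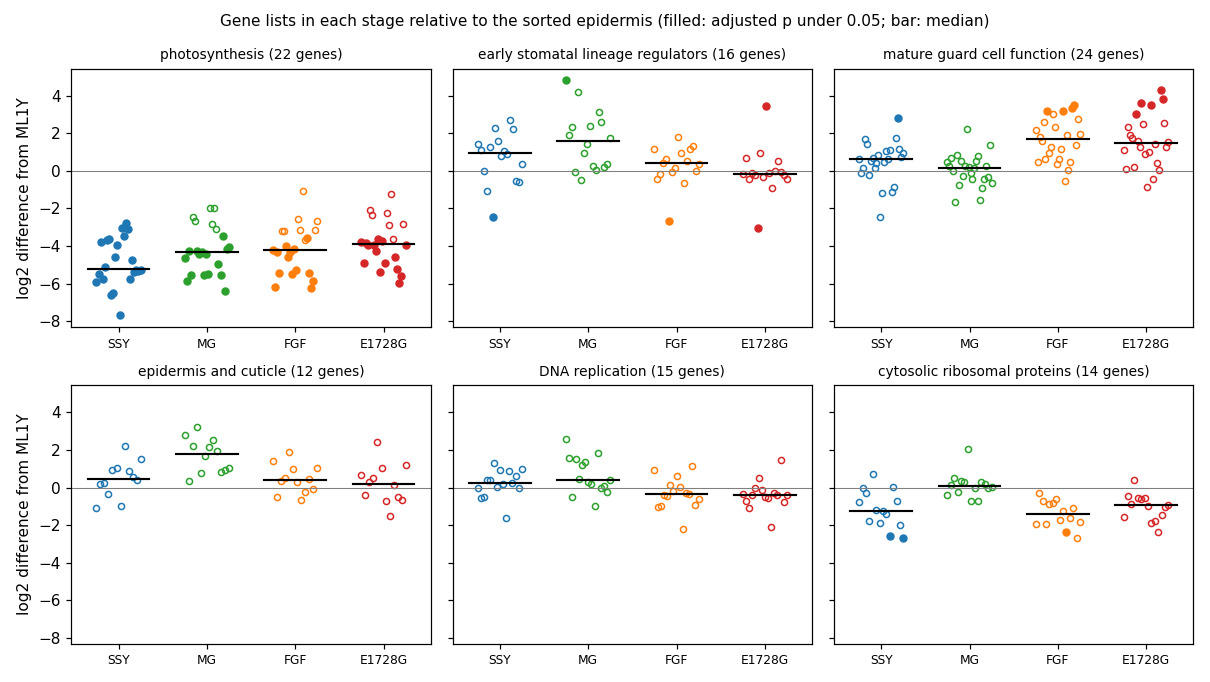
Log2 difference from ML1Y (vertical axes) of each member of 6 gene lists in the 4 stages (horizontal axes); filled points passed an adjusted p of 0.05, open points did not, and the bar is the list's median. Photosynthesis genes lay below 0 in every stage (medians -5.20, -4.30, -4.20 and -3.87), and mature guard cell genes were raised in FGF and E1728G (medians 1.68 and 1.48).

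The step from the early to the middle stage compared MG with SSY, with the stages named by marker line. Against ML1Y, SPCH did not pass in SSY and the early lineage list had no call (camera adjusted p = 0.153). These genes therefore do not show that the SSY sort was enriched for early-stage cells. MUTE (3.89 ± 0.58, adjusted p = 0.00872) and EPF1 (3.49 ± 0.53, adjusted p = 0.00925) rose, the members of the guard mother cell list that passed (2 of 11; 2 adjusted over the list alone). TGG1 fell by 2.54 ± 0.49 and the guard cell gene AT1G22690 by 3.12 ± 0.66 (2 of 24 fell, and 1 rose and 2 fell adjusted over the list alone). The list had no call (camera adjusted p = 0.19). EPF2, the peptide that limits entry into the lineage, rose by 2.34 ± 0.57 (1 of 16 early lineage regulators, 4 adjusted over the list alone). That list was raised (camera adjusted p = 0.0186, adjusted p = 0.258 with an estimated correlation). Cell cycle genes among those that passed were CYCD3;1 (2.81), the cytokinesis syntaxin KN (2.89), PCNA1 (2.58) and MCM2 (2.17), without a call for the mitotic or DNA replication lists (camera adjusted p = 0.918 and 0.232). In the mitotic list 1 of 25 genes passed (3 rose and 1 fell adjusted over the list alone), and 14 had negative differences. In the DNA replication list 2 of 15 passed (2 adjusted over the list alone), and 6 had negative differences.

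The lipid-related genes GPAT4 (3.86), LTP1 (3.13), ABCG12 (3.59) and CYP86A8 (4.64), the last a cutin hydroxylase, rose. Of 12 genes in the epidermis and cuticle list 3 rose (4 adjusted over the list alone), and the list was raised (camera adjusted p = 0.0118, adjusted p = 0.393 with an estimated correlation). RPS5A rose (3.90; 3 adjusted over the list alone), and 13 of 14 ribosomal protein genes had positive differences (camera adjusted p = 0.00449, adjusted p = 0.258 with an estimated correlation). Of 13 wound and touch genes 0 passed (0 adjusted over the list alone), and the list was higher (camera adjusted p = 0.0111, adjusted p = 0.259 with an estimated correlation). Further rises were PHB6 (5.09), the kinase gene MAPKKK18 (4.90), PI4K GAMMA 7 (4.69), the mitochondrial superoxide dismutase MSD1 (4.42), the syntaxin SYP61 (4.40), the peptide receptor PEPR1 (4.40), RAP2.6 (4.29) and HAB2 (3.62). LCR6 (-5.12), LCR20 (-5.04), NSI (-4.88), TED6 (-4.17), PM-ANT (-3.88), EXT4 (-3.81), the chloroplast superoxide dismutase CSD2 (-3.76), PP2-A3 (-3.60) and TTG2 (-3.34) fell.

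MG had 522 genes higher and 112 lower than SSY. The total ranged from 68 to 833 when single libraries were left out, with 833 without SSY replicate 1 (529 higher, 304 lower), 708 without MG replicate 1 (668 higher, 40 lower), 68 without MG replicate 2, 210 and 203 without ML1Y replicates 1 and 2, and 305 and 308 without SSY replicates 2 and 3. It was 2 when only the groups compared were fitted, 145 with library weights and 293 with quantile normalization. Of 31 named genes that passed, CYP86A8, LCR20, NSI and PM-ANT (4 genes) did so in every leave-one-out fit. Of the list calls for this step, only that of the ribosomal genes held in each of those fits. Without MG replicate 1 the other 3 ended, as did the early lineage call without SSY replicate 1 and the cuticle call without SSY replicate 3. All 4 ended with the filter at 50, and the early lineage and cuticle calls with quantile normalization.

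From the middle to the late stage, MUTE fell by 4.57 ± 0.64 (adjusted p = 0.024) and EPF1 by 3.29 ± 0.58 (adjusted p = 0.0391), while TGG1 rose by 3.23 ± 0.53 (adjusted p = 0.0297) and AT1G22690 by 4.28 ± 0.72 (adjusted p = 0.031). TGG1 and AT1G22690 were the 2 of 24 mature guard cell genes that passed (7 adjusted over the list alone). The list rose, with 22 of 24 differences positive and a median of 1.58 (camera adjusted p = 1.47e-11, adjusted p = 0.0149 with an estimated correlation). FAMA, at 14.47 ± 0.62 in FGF and 10.21 ± 0.55 in MG (n = 2 each), did not pass (adjusted p = 0.0645), though it did without SSY replicate 1 (adjusted p = 0.0452) or SSY replicate 2 (adjusted p = 0.04). CYCD3;1 fell by 3.38 ± 0.51. The mitotic list was lower with 0 of 25 genes past the threshold, 0 adjusted over the list alone (camera adjusted p = 0.000675, adjusted p = 0.258 with an estimated correlation). The DNA replication list was lower with 0 of 15, 4 adjusted over the list alone (camera adjusted p = 8.69e-05, adjusted p = 0.258 with an estimated correlation). Early lineage regulators were lower with 0 of 16, 6 adjusted over the list alone (camera adjusted p = 3.06e-05, adjusted p = 0.076 with an estimated correlation). All 14 ribosomal protein genes had negative differences, with 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 2.04e-06, adjusted p = 0.076 with an estimated correlation). The epidermis and cuticle list was lower with 0 of 12, 2 adjusted over the list alone (camera adjusted p = 0.000253, adjusted p = 0.283 with an estimated correlation). The mitotic, DNA replication and cuticle calls ended without MG replicate 1.

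The aldehyde oxidase gene AO1 (4.27), RING (3.62) and LigB (3.19) rose, and IGMT4 (-4.54), the methyl cycle gene SAHH2 (-4.37), CYP86A8 (-4.29), POLA3 (-3.86) and MBD11 (-3.40) fell. In total 18 genes were higher and 23 lower in FGF than in MG, against 2493 at an unadjusted p under 0.05. None of the genes named for this step passed in every leave-one-out fit. The total ranged from 0 to 259: it was 0 without FGF replicate 2, 19 without FGF replicate 1 (16 higher, 3 lower), 259 without MG replicate 1 (19 higher, 240 lower), 13 without MG replicate 2 (1 higher, 12 lower), 4 without either ML1Y library, and 26 and 24 without E1728G replicates 1 and 2. It was 1 with quantile normalization and 1 when only the groups compared were fitted, and more genes were higher than lower with the filter at 50 (33 and 29), with library weights (57 and 53), without all SSY libraries (30 and 18) and without SSY replicate 1 (21 and 20), 2 (27 and 20) or 3 (18 and 17).

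Between the late stage and mature guard cells, 3 genes passed, all higher in E1728G, and 0 were lower (limma; 1057 genes at an unadjusted p under 0.05). They were the mitochondrial import gene TIM17-1 (4.33 ± 0.50, adjusted p = 0.00585), the glycine-rich protein gene GRP9 (3.34 ± 0.45, adjusted p = 0.0266) and AT3G12502, the antisense transcript at HCHIB (6.70 ± 0.76, adjusted p = 0.00585), which has no symbol and was named after its value was seen. FAMA stood at 11.24 ± 0.37 in E1728G and 14.47 ± 0.62 in FGF (n = 2 each; adjusted p = 0.717). No member of the mature guard cell list passed (0 of 24, 0 adjusted over the list alone), and its median difference was 0.06 (camera adjusted p = 0.882). All 8 heat shock genes had negative differences, with 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.000177, adjusted p = 0.373 with an estimated correlation). That call ended without FGF replicate 1, and ended with a change of direction without E1728G replicate 1. Of 15 abscisic acid signalling genes 0 passed (0 adjusted over the list alone), and the list was lower by the preset test (camera adjusted p = 0.0255, adjusted p = 0.261 with an estimated correlation). So were the 4 marker line genes, of which 0 passed (1 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.189 with an estimated correlation). Both calls ended without FGF replicate 2, the first also without E1728G replicate 1 and the second without E1728G replicate 2. The lowest difference among the marker line genes was that of FAMA (-3.23), of which the FGF line carries a fusion. The call of that list is therefore not independent of the marker line. The gene count ranged from 1 without FGF replicate 2 to 83 without E1728G replicate 2 (80 higher, 3 lower) and was 15 without FGF replicate 1. The direction turned without either FGF library, with 2 higher and 13 lower without replicate 1 and the only call lower without replicate 2, and 0 genes passed when only the groups compared were fitted.

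**Figure D3:**
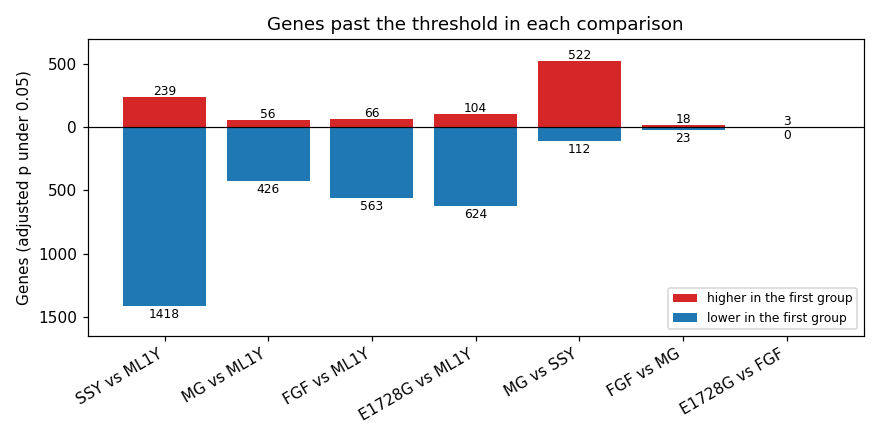
Number of genes past an adjusted p of 0.05 (vertical axis) in each of the 7 comparisons (horizontal axis), higher in the first-named group above 0 and lower below 0. Most genes that passed were lower in the stages than in ML1Y (1418 of them in SSY), and 3 passed between E1728G and FGF.

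Over the 4 stages, 976 genes varied (F test). Of these, 317 had their highest mean in E1728G, 299 in MG, 237 in FGF and 123 in SSY, and 605 had their lowest mean in SSY. The count was 343 to 1024 when single libraries were left out, and it was 349 and 343 without ML1Y replicates 1 and 2, 463 and 451 without SSY replicates 2 and 3, 466 without MG replicate 2, 597 and 478 without FGF replicates 1 and 2, and 404 without E1728G replicate 1. Of 126 list tests, 33 passed with the preset correlation and 7 with an estimated one: photosynthesis in each of the 4 stages against ML1Y, and mature guard cell function in FGF and in E1728G against ML1Y and in FGF against MG. Apart from the photosynthesis list, which was also the planned marker list for mesophyll, the lists of markers of other tissues passed in no comparison. Their members XCP2 and TTG2 passed as given above. The lowest camera adjusted p was 0.0835 for vasculature, 0.19 for trichome and 0.313 for meristem and leaf primordium growth. The D-type cyclins and CDK inhibitors (lowest adjusted p = 0.349) and the Polycomb and DNA methylation genes (0.0774) did not pass either.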

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

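Library weights, leaving out all SSY libraries and adding 1 before the log were chosen after seeing the data, and the other alternatives were planned. With library weights, 983 genes passed for MG (222 higher), 2430 for FGF (730 higher) and 2178 for E1728G (630 higher) against ML1Y. The counts were 145 for MG against SSY, 110 for FGF against MG, 15 for E1728G against FGF, and 620 over the stages. Without all SSY libraries, 1119 genes passed for E1728G against ML1Y, 0 for E1728G against FGF, and 107 over the remaining 3 stages. Fits of only the groups compared gave 901 genes for SSY (32 higher), 1455 for FGF (362 higher) and 1208 for E1728G (265 higher) against ML1Y. They gave 2 for MG against SSY, 1 for FGF against MG, 0 for E1728G against FGF and 347 over the stages. Quantile normalization gave 293 for MG against SSY, 1 for FGF against MG (100% higher, against 43.9% of 41) and 559 over the stages, and it moved the median of all genes for SSY against ML1Y to 0.14. FGF against MG gave 20 genes with no filter and 62 with a filter at 50. With an estimated correlation 7 list tests passed, all of them past the threshold under every alternative. With the replicate number as a block, 177 genes passed for MG against SSY, 2 for FGF against MG and 348 over the stages, and the other 5 comparisons stayed within 1.5 times. Of the 33 list tests that passed with that block, 31 were the same: the ribosomal call for SSY against ML1Y and the cuticle call for MG against SSY ended, and guard mother cell and mitotic calls for SSY against ML1Y appeared. The labels do not say whether same-numbered libraries share more than a number. Their deviations correlated between -0.08 and 0.03 across genes over 20 pairs. In groups of 2 libraries the deviations mirror each other, so many of these pairs repeat the same value. Correlations this low cannot exclude a shared batch. The main fit gave each gene 1 spread over all groups, though SSY libraries varied more than the others. Its median standard error was 0.587 in the comparisons with SSY and 0.643 in the rest. Library weights were 0.510 to 0.609 in SSY and 2.08 in ML1Y. How far unequal spread accounts for the shifts under the alternatives was not tested. Leaving out single libraries, where a lone sample is assumed to vary like the other groups, gave 299 to 1849 genes for SSY, 36 to 629 for MG, 87 to 719 for FGF and 93 to 821 for E1728G against ML1Y, 68 to 833 for MG against SSY, 0 to 259 for FGF against MG, 1 to 83 for E1728G against FGF, 343 to 1024 over the stages and 23 to 37 list tests. Of the values of named genes under all alternatives, 3535 kept their side of the threshold, 656 lost it, 8 gained it, and no call changed sign. The 8 were FAMA in FGF against MG (filter at 50, library weights, without all SSY, without SSY replicate 1 or 2) and in E1728G against ML1Y (only the groups compared, library weights, without all SSY). Part of this outcome was fixed in advance. Genes that passed had no overlap between the libraries of the groups compared. Leaving out libraries, weighting them or fitting only those groups therefore could not change the sign of a main call. The 2-fold minimum could change no call, since the smallest absolute difference that passed was 1.45. DESeq2 and edgeR need whole reads, which could not be recovered, and were not run. Robust moderation has no counterpart in the list test, and the 2-fold minimum none in the F test or the list test. Depth is unknown, so what it limits cannot be stated.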

Other observations

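The further gene groups below were chosen after the results were seen, and the test of guard cell shares was written after the levels of TGG1, AHA5, KAT2 and HT1 had been seen. The tests on EPFL9 and on genes high in 1 library were written after the patterns but before the values they use were seen. Besides the photosynthesis list, 6 further gene groups were tested over the 7 comparisons (42 camera tests). Photorespiration genes were lower in every stage than in ML1Y: of 12, 11 fell in SSY and in MG and 10 in FGF and in E1728G (medians -5.33, -4.54, -4.63 and -4.59, adjusted p = 0.00634 with an estimated correlation in each). Calvin cycle genes did the same, with 11, 6, 8 and 8 of 12 falling (medians -4.90, -3.66, -4.01 and -3.89, adjusted p = 0.00639, 0.00639, 0.00634 and 0.00639 with an estimated correlation). Both groups hold genes already named for large drops, GOX1, GGT1 and HPR in the first and FBA1, FBA2, GAPA-2 and SBPASE in the second. Their tests are therefore not independent of those drops. Chloroplast-encoded genes had lower medians of -2.77, -2.50, -2.38 and -2.45 over 114 genes, of which 59, 18, 23 and 20 fell (adjusted p = 0.0629 with an estimated correlation in each). The RNA was enriched with oligo-dT beads, and how evenly this captured organelle-encoded transcripts across libraries was not tested.

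The chloroplast-encoded genes thus had no call with an estimated correlation. The same held for the mitochondrion-encoded genes (lowest adjusted p = 0.713 with an estimated correlation over the 7 comparisons), the defensin-like LCR genes, of which 2 of 31 fell in MG against SSY and 26 had negative differences (adjusted p = 0.0629 with an estimated correlation), and pseudogenes, with a median of 0.51 for SSY against ML1Y over 4040 genes, of which 45 rose and 26 fell (adjusted p = 0.118 with an estimated correlation).

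Photosynthesis transcripts were higher in the sorted epidermis than in each lineage stage. Mesophyll protoplasts in the ML1Y sort are a candidate explanation, since EPFL9, a peptide gene expressed in the mesophyll and outside the photosynthesis list, averaged 4.67 ± 0.54 (SD, n = 2) in ML1Y and 3.12 in the highest stage, a difference of 1.552 that the explanation needs. EPFL9 is low, its differences did not pass in the limma test (adjusted p from 0.0613 to 0.195), and the sort selected YFP-positive protoplasts. A lower chloroplast gene expression in lineage cells than in pavement cells remains open and was not tested.

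TGG1 was high in the early-stage sort. Guard cells in that sort would bring all their transcripts. Their share was read from the 52 other genes raised in FGF and at least 1 log2 unit higher in E1728G than in ML1Y. The guard cell gene AT1G22690 did not pass in FGF against ML1Y and is not among the 52. Its log2 difference for MG against SSY was -3.12, so it was also higher in SSY than in MG, and no share was read from it. The median implied share of the 52 genes was 2.79% (bootstrap interval -1.93% to 7.44%, 23 genes at or below 0%). That is under the bound of 23.48%, which is TGG1's implied share of 46.96% divided by 2. The interval came from resampling the genes, which share the same libraries, so it leaves out the spread between libraries. The bound was 35.1%, 15.1% and 23.7% without SSY replicates 1, 2 and 3 (upper interval ends 8.72%, 8.29% and 6.98%) and 29.2% with FGF as the profile of the admixed cells (upper end 6.67%), and single genes spread widely: AHA5 2.74% (0.0923% without SSY replicate 1, 5.15% without replicate 3), TGG2 12.8% (23.7% without replicate 2, 5.49% without replicate 3) and ABCG40 81.4% (15.1% without replicate 1, 145% without replicate 3). These values argue against guard cells as the whole source of TGG1 only if the other cells of the sort resembled ML1Y. That condition is uncertain, since SSY and ML1Y libraries had rank correlations of 0.764 to 0.795 across genes and 1657 genes differed. The source of FAMA, at 129% with E1728G and 11.8% with FGF as the profile, stays open. Myrosin cells, which express TGG1 but would need SPCH-YFP signal to be sorted, and an early onset of TGG1 also stay open and were not tested.

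Replicates of the early stage differed from each other more than other replicates did. Few molecules amplified per library is a candidate explanation, which predicts more genes at least 3 log2 units above every other library in each SSY library than in any other. The SSY libraries had 106, 155 and 115 such genes, and MG replicate 2 had 107. The prediction as written beforehand was missed by 1 gene, which is within counting spread, a criterion added after the counts were seen, so the explanation cannot be told apart from a more varied sort. A biological difference between the replicates was not tested.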
